A study of Mus musculus with 18 samples.

How the data were processed

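The series profiled chromatin from mouse pancreatic islets and islet tumours by ChIP-seq, in which DNA bound by a chosen protein or histone mark is pulled down with an antibody and sequenced. It holds 18 samples from 6 conditions: RIP-Cre mice, which carry Cre recombinase under the rat insulin promoter and served as controls, and mice with an islet-specific knockout of Men1, each at 2, 6 and 12 months of age. Men1 encodes menin, a subunit of histone methyltransferase complexes that place methyl groups on lysine 4 of histone H3. Each condition had 1 input library, 1 H3K4me3 library (a mark of active or poised promoters) and 1 H3K27me3 library (a mark of Polycomb repression). Peak lists of 2 samples were used here, H3K4me3 of control islets and H3K4me3 of Men1 knockout islets, both at 2 months. The other 16 samples were not analysed here.

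Per the labels' protocols, the tissue was fixed with formaldehyde, lysed and sonicated, and the precipitated DNA was made into Illumina libraries. The submitters' processing notes name Bowtie, MACS 1.4.2 and the mouse build mm9. Whether the input libraries served as control in peak calling, which filters were applied and whether animals were pooled are not given in the sources used here. Each deposited list gives a chromosome, a start, an end and a score per peak, with no header, no read counts and no signal values, so the depth of the libraries is unknown. The score is the authors' deposited value for each peak. The peaks carry MACS names, and MACS 1.4.2 writes the score as minus 10 times log10 of the peak's p-value. Read on that scale, the lowest deposited scores, 60.01 and 60.02, correspond to a p-value threshold of 1e-06, but the lists do not state the scale. Many peaks are tied at a score of 3100 and some score higher, so scores do not rank the strongest peaks. Scores were used to describe, rank or filter peaks within a list. Some values rest on scores of both lists, such as shares or counts of peaks beyond a common score, and the scores of partner peaks. Without the depths, such differences between the lists cannot be read as differences in H3K4me3. Each list was matched to its sample by genotype, age and mark in its name, since it was deposited for the series as a whole. The names also carry an unexplained word, "2nd", so that it is not known whether a list holds a repeat experiment. No per-sample column was left unused (0 columns).

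Each peak was kept as deposited. Within each list 0 peaks overlapped one another. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and otherwise a one-list peak. The overlap to be met by peaks at random positions was taken from 100 circular shifts of one list within each chromosome (seed 1). Widths were compared over pairs in which 1 peak of each list overlapped only the other, as log2 of knockout over control width. To include peaks that were split in one list, touching peaks of both lists were also joined into regions and the length covered by each list within a region was compared. Medians are given with 95% order-statistic (binomial) intervals, and shares with exact (Clopper-Pearson) 95% binomial intervals. These intervals give the precision of a median or share, treating the peaks of this pair of libraries as independent. They are not the spread over peaks, and they are too narrow where neighbouring peaks vary together. They do not cover variation between animals or libraries. With 1 library per genotype there is no replicate check, and no p-value was computed.

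Regions were named by a rule fixed before the data were examined: per direction, the 8 peaks with the highest score that had no peak of the other list within 5 kb (5000 bp). The rule named genes where an annotation of the build of the peak lists was at hand. The gene table used here describes another build (GRCm38), so its positions could not be set against mm9 peaks. Promoter counts, the fixed gene lists and the level of H3K4me3 at Men1 itself were therefore not analysed, and regions are given by mm9 position, counted from 1. Regions singled out after their values were seen are said to be so. The alternatives fixed before the data were examined were a reciprocal overlap of 50%, a distance of 1 kb counted as shared, the top 50% of a list by score (at or above its median score), equal numbers of peaks, merging of peaks within 1 kb, autosomes only, and other widths for the broadest class.

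The overlap and width functions were tested on simulated data. A list made from the 21905 control peaks with 200 peaks removed and a true median log2 width ratio of -0.2 gave back 198 of the removed peaks as one-list peaks, 0 false ones, and a median of -0.20. Each kept peak was rescaled around its own midpoint, so false one-list peaks could hardly arise. Misses near the caller's threshold and split peaks were not simulated, so the test checks the functions and not the rate of such misses. The functions and bedtools 2.31.1 counted the same 19130 shared control peaks. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.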

Results

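H3K4me3 was mapped by ChIP-seq in pancreatic islets of 2-month-old RIP-Cre control mice and of mice of the same age with an islet-specific knockout of Men1, with 1 library per genotype. At this age the labels describe the knockout tissue as islets. Only the 12-month knockout samples, which were not analysed here, are described as tumour. The control list held 21905 peaks that covered 42.4 Mb of the mouse genome (mm9), and the knockout list held 21434 peaks that covered 38.3 Mb, or 90.1% of the control length. Peak widths ranged from 363 to 21936 bp in control islets and from 314 to 22264 bp in knockout islets. A score of 3100 or more was reached by 41.3% of control peaks and by 33.4% of knockout peaks. Read depth is unknown for both libraries, and there are no replicates, so the differences below are differences between this pair of libraries. The mice were of a mixed strain background, so a peak found in one list alone may also reflect sequence differences between animals.

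The first comparison asked which H3K4me3 regions were marked in both genotypes and which in one alone. Most of the H3K4me3 landscape was common to control and Men1 knockout islets. Of the control peaks, 19130 (87.3%, exact 95% interval 86.9 to 87.8) overlapped a knockout peak. Of the knockout peaks, 19567 (91.3%, interval 90.9 to 91.7) overlapped a control peak. Control peaks shifted at random along their chromosomes met a knockout peak in 3.12% of cases on average, and shifted knockout peaks met a control peak in 3.23%. The shifts could place peaks anywhere on a chromosome, at promoters or not. These values are thus a low floor and do not measure how alike the genotypes were. Counted by length, 35.5 Mb were marked in both lists, which is 83.5% of the control length and 92.7% of the knockout length.

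Peaks found in one genotype alone were mostly weak and narrow. There were 2775 control-only peaks, with a median score of 98.4 and a median width of 805 bp, against 2802 and 1940 bp for the control peaks that were shared. There were 1867 knockout-only peaks, with a median score of 85.0 and a median width of 665 bp, against 1965 and 1739 bp for shared knockout peaks. A score under 100 was found for 51.1% of control-only and 62.5% of knockout-only peaks. One-list peaks made up 5.65% of the length marked in control islets and 3.56% of that marked in knockout islets. In each list 2 one-list peaks reached the median score of their own list. Near another peak, 22.5% of control-only peaks and 22.7% of knockout-only peaks lay within 5 kb of a peak of the other list. A peak just above the caller's threshold can be missed in a second library by chance, and without replicates the share of such misses was not measured. Between the top 50% of each list by score, 654 control peaks and 397 knockout peaks had no partner, but all except 2 in each list overlapped a lower-scoring peak of the other list.

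**Figure D1:**
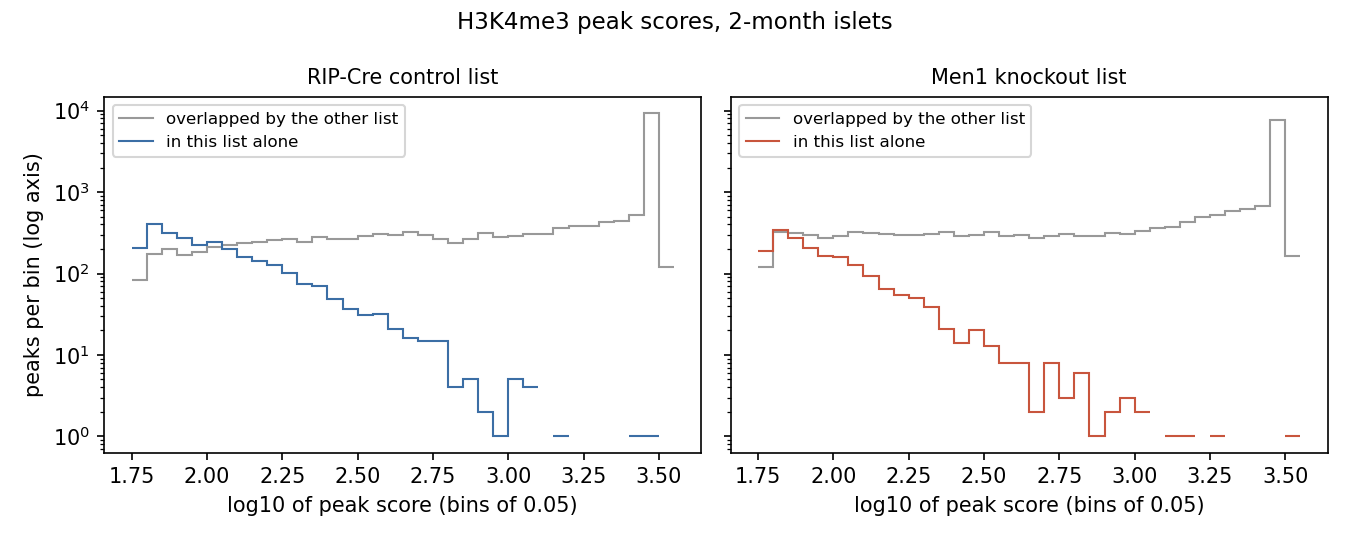
Number of H3K4me3 peaks per bin of log10 score (horizontal axis, bins of 0.05; vertical axis logarithmic) in the control list (left) and the Men1 knockout list (right). Grey lines are peaks overlapped by the other list and coloured lines are the 2775 control-only and 1867 knockout-only peaks, which lie mostly at the low end, while the grey spike on the right holds the peaks tied at 3100.

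The highest-scoring H3K4me3 peaks of one genotype alone were mostly not among the higher-scoring peaks of their list. Of the 8 named in each direction, 6 scored under the median of their own list (1988 in control and 1591 in knockout islets). In control islets, the highest-scoring such region was a 5408 bp peak on the X chromosome (46023673 to 46029080) with a score of 2876. The nearest knockout peak lay 18.5 kb away. A 1411 bp peak on chromosome 17 (36304242 to 36305652) followed with a score of 2672, and another control-only peak lay on the same chromosome at 36178720 to 36180801, with a score of 1060. The remaining control-only regions among the 8 named had scores between 1113 and 1171. They were on chromosome 17 at 44271214 to 44273616 and at 6474942 to 6476734, on the X at 105858358 to 105860739, on chromosome 7 at 30927910 to 30929491, and on chromosome 1 at 160884277 to 160889268. The chromosome 1 region was 4992 bp wide and 272 kb from any knockout peak.

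In knockout islets, the highest-scoring region without a control peak was on chromosome 7 (142290278 to 142293453). It was 3176 bp wide, scored 3184, and lay 159.5 kb from the nearest control peak. A 1631 bp peak on chromosome 9 (4795195 to 4796825) scored 1946 and was 239 kb from any control peak. A 3546 bp peak on chromosome 6 (126592692 to 126596237) scored 1474, and a 1843 bp peak on chromosome 3 (62406642 to 62408484) scored 1315. The other named knockout-only regions scored between 984 and 1119. They were on chromosome 17 at 31028682 to 31031173, on chromosome 8 at 27409079 to 27411697, and on the X at 61528785 to 61530710 and 51277514 to 51280367. The X region at 61528785 was 2375 kb from the nearest control peak. At a score of 300 or more and with no peak of the other list within 5 kb, there were 139 control-only and 59 knockout-only regions. Such counts depend on how scores compare between the lists. Shared control peaks with a score of 600 to under 1200 had knockout partners with a median score of 616. Shared knockout peaks in that range had control partners with a median score of 1167. A common score was therefore not equally strict in both lists, and 139 against 59 cannot be read as loss of H3K4me3.

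The second comparison asked whether shared regions were equally wide. H3K4me3 peaks were slightly narrower in the Men1 knockout list. Over 18299 one-to-one pairs the median width was 1923 bp in control and 1764 bp in knockout islets. The median log2 ratio of knockout over control was -0.11 (95% interval -0.117 to -0.110), so that the median knockout peak had 92.4% of its control width. The knockout peak was narrower in 13513 pairs (73.8%), wider in 4761 (26.0%) and equal in 25. Both borders lay further in, by a median of 66 bp on the left and 70 bp on the right. The spread between pairs was larger than the shift, with an SD of 0.29 on the log2 scale. Because there is no second library of either genotype, it is not known how far the median would differ between libraries of 1 genotype.

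The relative narrowing was greatest at narrow peaks. The median log2 ratio was -0.22 (interval -0.245 to -0.196) in the narrowest 10% of pairs by mean width and -0.07 (interval -0.077 to -0.062) in the widest 10%. In base pairs the order was the opposite, with a median difference of -108 bp in the narrowest 10% and of -186 bp in the widest 10%. Pairs in which both peaks had a score of 3100 or more had a median log2 ratio of -0.09. The narrowing was present on all 19 autosomes, from -0.13 on chromosome 6 to -0.09 on chromosome 7. On the X chromosome the median was -0.14 (interval -0.169 to -0.118, 551 pairs).

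**Figure D2:**
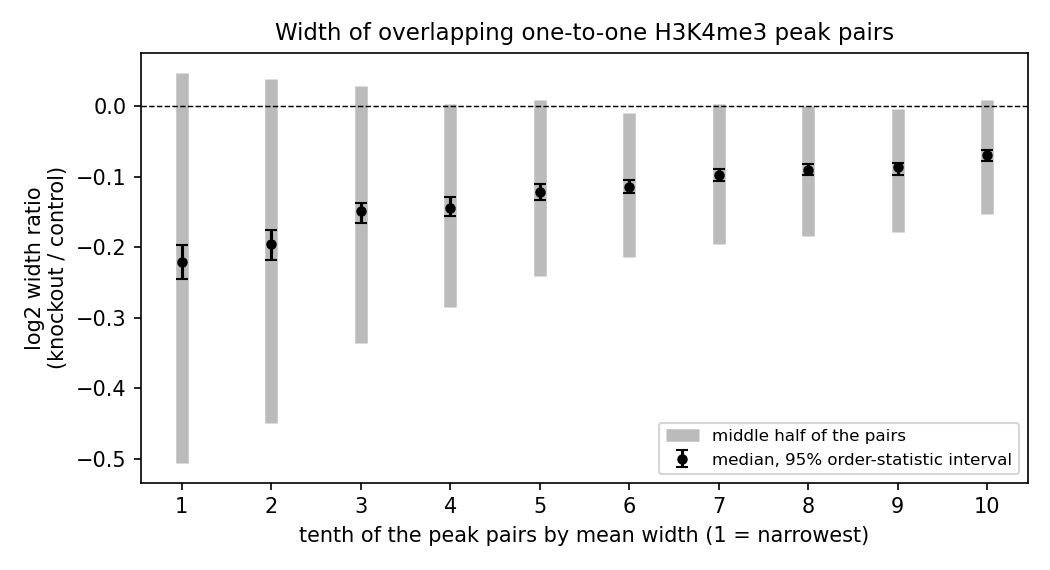
Log2 ratio of knockout over control peak width (vertical axis) in 10 equal classes of the 18299 one-to-one pairs by mean width (horizontal axis, 1 is narrowest). Points are medians with 95% order-statistic intervals and grey bars span the middle 50% of the pairs, and the medians lie below 0 in each class and move from -0.22 to -0.07.

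Control peaks were more often represented by several knockout peaks than the reverse. In the control list 565 peaks overlapped 2 or more knockout peaks, while 156 knockout peaks overlapped 2 or more control peaks. When touching peaks were joined into 18970 regions marked in both lists, 518 regions held more knockout than control peaks and 109 held fewer. The median log2 ratio of the covered length was -0.11 over these regions, as for the one-to-one pairs.

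The third comparison concerned the broadest H3K4me3 domains, a class that tends to lie at genes of cell identity. Most of these domains were called as broad peaks in both lists. Of the broadest 5% of control peaks (1095 peaks, 3881 bp or wider), 846 (77.3%, interval 74.7 to 79.7) overlapped one of the broadest 5% of knockout peaks (1071 peaks, 3628 bp or wider). All but a pair of them, 1093, overlapped some knockout peak. The broadest region lay on chromosome 2 (105505041 to 105528945), where the control list covered 23119 bp and the knockout list 22264 bp. The next in order of mean covered length were on chromosome 13 (117086937 to 117104794), with 17858 bp in control and 16083 bp in knockout islets, on chromosome 18 (83078391 to 83093336), with 14712 and 14493 bp, and on chromosome 2 (147006831 to 147021705), with 13690 and 14869 bp.

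Some broad domains differed far more than the median. These were singled out after their values were seen, as the extremes of the widest 10% of joined regions. On chromosome 13 (72095477 to 72102134) the control list covered 6658 bp and the knockout list 1981 bp, a log2 ratio of -1.75. A second domain on that chromosome (72763979 to 72770625) went from 6647 bp in control to 2598 bp in knockout islets. On chromosome 18 (11047954 to 11057401) the values were 9448 and 3752 bp, and on chromosome 6 (112435152 to 112441483) 6332 and 2335 bp. In the other direction the ratios were smaller. The largest in this class was 0.52 on chromosome 7 (56739282 to 56743344), with 2825 bp in control and 4063 bp in knockout islets. The pairs below were also singled out after their values were seen. Among one-to-one pairs of any width with a peak in the top 50% of its list by score, the greatest widening was on chromosome 4. There a control peak of 629 bp with a score of 68.2 (8781411 to 8782039) faced a knockout peak of 4428 bp with a score of 3100 (8781089 to 8785516). The greatest narrowing was on chromosome 7, where a control peak of 3361 bp with a score of 3100 (127317037 to 127320397) faced a knockout peak of 737 bp with a score of 81.1.

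**Figure D3:**
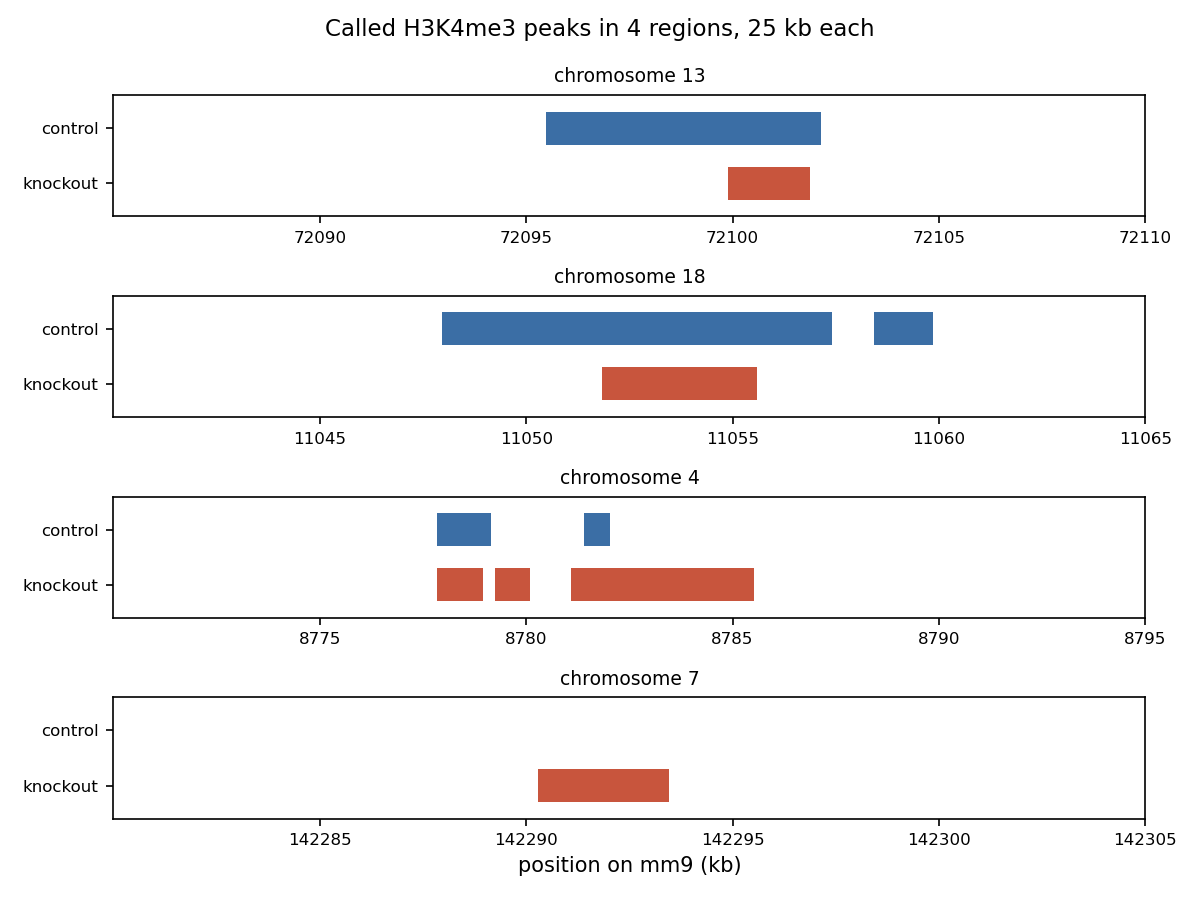
Called H3K4me3 peaks in the control (blue) and Men1 knockout (red) lists in 4 stretches of 25 kb, with mm9 position in kb on the horizontal axis. Bars are to scale. In the overlapping pair named in the text, the knockout bar is shorter on chromosome 13 (1981 against 6658 bp) and chromosome 18 (3752 against 9448 bp). It is longer on chromosome 4 (4428 against 629 bp), and the knockout bar on chromosome 7 has no control peak. The stretches on chromosomes 18 and 4 hold other peaks as well, on chromosome 4 a control peak of 1302 bp and knockout peaks of 1123 and 844 bp. The stretches on chromosomes 13, 18 and 4 were singled out after their values were seen.

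H3K4me3 peaks were distributed over the chromosomes alike. The exact 95% intervals of the share of peaks overlapped between the lists for all 21 chromosomes, and the largest difference was 0.19 percentage points. Most peaks were shared, so the chromosome shares of the lists are not independent and would be close in any case. The X chromosome held 2.90% of control peaks and 2.96% of knockout peaks. Each list held 3 peaks on the Y chromosome, and each of these was shared. The share of control peaks without a knockout partner ranged from 9.80% on chromosome 7 (interval 8.35 to 11.4) to 15.7% on chromosome 10 (interval 13.7 to 17.8) among the autosomes, and was 8.81% on the X (interval 6.72 to 11.3). For knockout peaks without a control partner the lowest autosomal share was 5.20% on chromosome 11 (interval 4.18 to 6.39) and the highest was 11.3% on chromosome 18 (interval 8.96 to 13.9).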

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

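The median width ratio stayed below 0 under each alternative run, while many sizes moved: 28 of the recomputed values stayed close to the value reported and 31 did not. Close means inside its 95% interval for a share or median and within 1.5 times for a count. The share of control and of knockout peaks that was shared came to 84.6% and 86.5% with a reciprocal overlap of 50%, 88.3% and 92.2% with a distance of 1 kb, 94.0% and 96.3% between the top 50% of both lists by score, 99.982% and 99.981% for the top 50% against the whole other list (so that the knockout share was no longer the higher), 88.6% and 90.7% with equal numbers of peaks, and 88.1% and 91.8% after merging. A score of at least 100 in both lists, an alternative added after seeing the data, gave 89.3% and 94.3%. One-list counts moved by over 1.5 times in these cases: 2899 knockout peaks with reciprocal overlap, 654 control and 397 knockout peaks between the top 50% of both, 2 and 2 for the top 50% against the whole list, and 1086 knockout peaks at a score of at least 100. The 2 one-list peaks per list at or above its median score became 89 control and 88 knockout peaks with reciprocal overlap, 654 and 397 between the top 50% of both, 1 control peak on the autosomes alone and 4 control peaks at a score of at least 100. The 654 and 397 come from leaving out lower-scoring partners, since the same peaks against the whole other list left 2 and 2. On the autosomes alone, the control-only X peak with a score of 2876 was left out. At a score of at least 100, the added peaks above the median were those whose partners scored under 100. At that score, 1167 of the 1867 knockout-only peaks were left out because they scored under 100. Shared knockout peaks whose control partners scored under 100 were added to the rest, which gave 1086. The cause of the other moves was not tested. The median log2 width ratio was -0.094 for pairs in the top 50% of both lists and -0.087 for pairs with both peaks at or above the tied score of 3100, the latter added after seeing the data. The share of the broadest control peaks found among the broadest knockout peaks was 71.9% for the top 2% and 80.2% for the top 10%. In the top 50% by score the X held 2.79% of control peaks (interval 2.49 to 3.12) and 2.53% of knockout peaks (interval 2.24 to 2.84). This is the opposite order to the whole lists (2.90% and 2.96%). The intervals of the lists overlapped in both cases, so these values establish no change of order.

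The alternatives for promoter windows, gene lists and annotation classes were not run, since no annotation of mm9 was used here. No paired analysis was possible because each genotype has 1 library. Depth is unknown, so it cannot be said which absent peaks were beyond detection, and no analysis without 1 library was possible.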

Other observations

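The length called as H3K4me3 peaks was summed over windows of 1 Mb in each list. The windows below were singled out after their values were seen, as the 5 lowest and the 2 highest ratios of 1356 windows with a mean covered length of 10000 bp or more. The median log2 ratio of knockout over control was -0.16 (SD 0.16 over windows). The lowest value was on chromosome 10 from 50000001 to 51000000, with 13770 bp in 5 control peaks and 6799 bp in 4 knockout peaks. On chromosome 2 from 115000001 to 116000000 there were 25615 bp in 9 control peaks and 12778 bp in 6 knockout peaks. On chromosome 13 from 72000001 to 73000000 there were 21403 and 11503 bp in 8 peaks each, with mean widths of 2675 and 1438 bp, and most of the difference lay in the pair of broad domains given for this chromosome in the report. On chromosome 18 from 11000001 to 12000000 there were 19727 bp in 7 control peaks and 11181 bp in 6 knockout peaks. On chromosome 17 from 44000001 to 45000000 there were 18024 bp in 9 control peaks and 10538 bp in 5 knockout peaks. The highest value was on chromosome 12 from 57000001 to 58000000, with 6558 bp in 5 control peaks and 13860 bp in 11 knockout peaks, at mean widths of 1312 and 1260 bp. Next was chromosome 7 from 77000001 to 78000000, with 9712 bp in 5 control peaks and 14877 bp in 12 knockout peaks. With so few peaks per window, 1 or 2 peaks can set a ratio, and no test of these windows against chance was made. The genes in them were not identified here.

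The tests on peak width and on higher-scoring one-list peaks below were chosen after the result was seen, and those on neighbouring regions before. The general narrowing of knockout peaks was genome-wide, with the interval of the median below 0 on 19 of 19 autosomes. A difference in depth or enrichment between the libraries and a genome-wide effect of genotype would both give this, and with 1 library per genotype they cannot be told apart. Another hypothesis, that the widest H3K4me3 regions lost a larger part of their length than others, met the opposite: the median log2 ratio was higher by 0.049 in the widest 10% (-0.070, interval -0.078 to -0.062) than in the other regions (-0.120, interval -0.123 to -0.117). In base pairs the widest 10% lost more, with a median difference of -197 bp against -146 bp. A loss of similar length in base pairs at each region would by itself give a smaller relative loss in wide regions. The width classes of the one-to-one pairs had already shown this order on largely the same peaks. The comparison therefore does not show whether broad regions were spared.

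Peaks of one list alone with a higher score than most such peaks were examined for a pair of technical explanations. At a score of 600 or more, which 64.8% of control and 63.3% of knockout peaks reached, 44 peaks had no peak of the other list within 5 kb and 38 had a partner scoring under 100, a ratio of 1.16. The lists differed, with 26 and 28 such control peaks (ratio 0.93) and 18 and 10 such knockout peaks (ratio 1.8). These ratios do not show whether the other library fell below the caller's threshold at the absent peaks. That explanation sets no expected ratio, so it stays open. Sequence differences between mice of the mixed 129, FVB and C57BL/6 background could place such peaks in clusters. Of the 198 peaks with a score of 300 or more (reached by 73.5% of control and 71.9% of knockout peaks) and no peak of the other list within 5 kb, 21.2% had another of the same list within 1 Mb, and draws of shared peaks matched on score gave a median of 15.2% (middle 95%, 9.09 to 22.2), so this explanation was neither favoured nor excluded. Genotype also stays open.

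Neighbouring H3K4me3 regions shared a small part of their width change. After removing the median of each width class, the log2 ratios of regions 20 to 100 kb apart correlated across regions with Pearson's r = 0.038 (27863 region pairs, which are not independent), above each of 1000 shuffles within chromosome and width class (highest 0.025). Chance variation that depends only on chromosome and width class is therefore not enough for this correlation. It was 0.075 at 5 to 20 kb, 0.014 at 100 to 500 kb and 0.0051 at 500 to 2000 kb, where the middle 95% of shuffles reached 0.0044 and the highest 0.0068, so a slow trend along the chromosomes could not be ruled out as a contributor, although the value at that distance was under that at 20 to 100 kb. A candidate explanation is regulation of neighbouring regions together. These lists cannot separate it from local differences in mappability or base composition. Similar scores of neighbouring peaks also stay open as an explanation, since the shuffles did not keep score. The median log2 width ratio of one-to-one pairs was -0.087 with both peaks at or above the tied score and -0.141 for the others. These medians were not adjusted for width.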
